A study of Homo sapiens with 10 samples.

How the data were processed

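Poly(A) RNA from 2 human lung adenocarcinoma cell lines, A549 and NCI-H1944 (H1944 below), was sequenced in 10 libraries. Per the labels, RNA was taken up in TRIzol, libraries were made with a VAHTS kit after poly(A) selection, and paired-end reads came from a NovaSeq. Per the labels, the authors' tools were Trim Galore 0.5.0 for trimming, HISAT2 2.1.0 for alignment to hg38, featureCounts 1.6.4 for counting and DESeq2, without a version. Strand, annotation and the treatment of reads with several alignments were not stated, so values of overlapping or antisense genes and of near-identical paralogs are uncertain. The deposited values are raw counts per gene symbol, with no normalization by the authors, for 28281 symbols in 1 table per line.

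Groups were WT and APEX1 knockout (KO) within each line. The names of 3 A549 columns (65, 16 and 66) carry no genotype. They were taken as the A549 KO group because the labels left no other group for them, and which number belongs to which labelled replicate is unknown. No per-sample column was left out of the comparisons. Nothing in the labels says whether libraries of a group came from separate cultures or clones, so every p-value here measures only the spread between these libraries, which may be technical. No paired analysis was possible for A549 because the KO numbers do not match the WT numbers. For H1944 a block on the replicate number was an alternative.

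Totals ran from 18314224 to 30219850 counts per library. A count of 0 was read with an upper limit of 3 counts per library, which is 0.0993 to 0.164 library-size-scaled counts (CPM). Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

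Genes were kept by filterByExpr (minimum count 10) and scaled by TMM. KO was compared with WT by the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 3 against 3 libraries in A549 and 2 against 2 in H1944. The difference between lines (A549 change minus H1944 change) came from 1 fit of all 10 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold, with a second count at an absolute log2 fold change of at least 1. Adjusted p-values without another tool's name are from edgeR. Standard errors (SE) are approximate, the absolute log2 fold change over the square root of F. Single genes of A549 also had 2-sided exact permutation tests. Fold changes against a group with 0 counts are lower bounds against 3 counts per library, and those against 1 to 3 counts have 95% exact binomial (Clopper-Pearson) intervals of the count ratio.

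There were 27 gene lists fixed before the data were examined. Of these, 26 had at least 3 tested members in each line; the list of mitochondrially encoded mRNAs was not tested. Lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. With so few libraries, camera at an estimated correlation has few degrees of freedom and little power. In H1944 the interferon list's estimated correlation was -0.0366, yet its unadjusted camera p went from 1.6e-15 to 0.0122. A list that does not pass there is therefore not shown to be unchanged. Fry asks whether members changed, not whether they changed more than other genes. The study's title names the urea cycle, so the direction of that list is not independent evidence. Named genes followed a rule fixed before the data were examined. It takes APEX1, the tested urea cycle genes, and up to 10 largest rises and falls per line with WT and KO libraries apart and a mean of at least 5 CPM. It adds up to 4 members with the smallest adjusted p of each list described, the 5 largest differences between lines each way, and genes called in both lines. MAGEA3, NTRK3, KRT8, KRT18, FOS, EGR1, COL1A1, COL3A1 and DCN are outside it and were named after their values were seen, and some genes that the rule names are not used here.

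The fits were tested on simulated data, with counts drawn for the real genes and 200 genes changed. In a first version each gene had its shrunken dispersion, and with that 16.7% of the A549 calls in 8 draws were unchanged genes. The dispersions drawn were too even: the median prior degrees of freedom were 9.74 in the A549 draws against 2.96 in the real A549 fit. After this was seen, dispersions were also drawn around those values with the spread of the real fit, per line, which gave 4.27 in A549. With these, edgeR recovered 0 of 528 4-fold changes in A549 over 8 draws and called 1 gene, an unchanged one. DESeq2 1.42.0 recovered 68.9% of 4-fold changes in A549 over 4 draws, but 52.0% of its calls were unchanged genes. In H1944 edgeR recovered 60.8%, 76.3% and 93.2% of 1.5-fold, 2-fold and 4-fold changes, and 10.4% of its calls were unchanged genes, above the 5% aimed at. For the difference between lines edgeR recovered 0 of 528 4-fold changes and made no false call in 8 draws, while 34.5% of DESeq2 calls were unchanged genes. Among unchanged genes, 4.72% in A549 and 4.95% in H1944 had an unadjusted p under 0.05 in edgeR. The draws held no processing sets of A549 libraries, and the share of false calls depends on the number of changed genes. In H1944 the median prior degrees of freedom were 29.0 in the draws with the spread, against 18.6 in the real fit.

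Alternatives fixed before the data were examined were DESeq2 size factors, library size only, no low-count filter, a filter of 1 CPM in every library of a group, DESeq2, limma-voom, the replicate block, all 10 libraries in one fit, leaving out each replicate, and stricter thresholds. Chosen after seeing the data were a processing set of the A549 libraries as a covariate, the larger A549 set alone, and leaving out 20 ribosomal RNA genes. The processing set of an A549 library was given by whether it had reads on RNA28SN4, a copy of the 28S ribosomal RNA gene. Gene positions, lengths, GC content and G-quadruplex motifs (4 runs of at least 3 guanines, or 4 of cytosines for the other strand, with loops of up to 7 bases) came from 1 spliced transcript per gene in a GENCODE annotation of the hg38 assembly. Motifs were searched in the first 500 bases of the transcript, and promoters upstream of it were not searched. Python 3.11.15 with matplotlib 3.10.9 drew the figures.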

Results

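Messenger RNA was measured in 2 human lung adenocarcinoma cell lines, A549 and NCI-H1944 (H1944 below), with APEX1 intact (WT) or knocked out (KO). APEX1 encodes APE1, the main endonuclease of base excision repair and a redox regulator of transcription factors. The title of the study names APE1, urea cycle genes and G-quadruplexes. A549 had 3 WT and 3 KO libraries and H1944 had 2 and 2. Total counts were 18314224, 24358934 and 23589799 in A549 WT 1, 2 and 3, and 23316585, 19578197 and 23336357 in A549 KO 16, 65 and 66. They were 22144904 and 20754740 in H1944 WT 1 and 2, and 28950423 and 30219850 in H1944 KO 1 and 2. The 3 A549 KO libraries are known by column numbers that state no genotype and were assigned to KO because the labels left no other group for them.

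The A549 libraries fell into 2 sets that cut across genotype. WT 1 and KO 65 had 264 and 304 CPM of RNA28SN4, a copy of the 28S ribosomal RNA gene, and WT 2, WT 3, KO 16 and KO 66 had 0 counts of it. Ribosomal RNA genes took 0.284% and 0.337% of the counts in WT 1 and KO 65, 6.45% and 6.46% in WT 2 and WT 3, 7.18% in KO 66 and 14.2% in KO 16. The first principal component, with 64.3% of the variance, separated WT 1 and KO 65 from the other libraries. The urea cycle genes, the lists that passed and some single genes of A549 are therefore also given within these sets, as KO 65 against WT 1 and as KO 16 and KO 66 against WT 2 and WT 3. Within the larger set KO 16 stood apart, at 12.5 on the first component against 47.0 to 54.2 for KO 66, WT 2 and WT 3. From WT 2 and WT 3 it differed by a chi-square of 153 and 150 per gene, against 32.0 and 30.6 for KO 66. Values of KO 16 within its set may therefore also hold a difference between libraries other than genotype. In H1944 ribosomal RNA genes took 0.139% to 0.316%. Libraries of 1 group differed by more than sampling noise in each pair, least in A549 WT 2 and WT 3 (chi-square of 1.90 per gene), which does not tell separate cultures from repeat preparations.

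The first question was what loss of APE1 does to urea cycle genes in A549. APEX1 mRNA and CPS1 mRNA were lower in each of the 3 KO libraries than in each of the 3 WT libraries, but neither difference passed the test over all genes. APEX1 (chromosome 14, 20455191 to 20457772, hg38) measured 220 ± 46.2 CPM in WT and 76.9 ± 26.8 CPM in KO (SD, n = 3 each), a log2 fold change of -1.51 with an SE of 0.30 and an edgeR adjusted p of 0.521. CPS1, which makes carbamoyl phosphate in the first step of the cycle (chromosome 2, 210477682 to 210679107), measured 29.02 ± 15.6 and 4.79 ± 3.03 CPM, a log2 fold change of -2.60 with an SE of 0.58 and an edgeR adjusted p of 0.567. ASS1, which makes argininosuccinate (chromosome 9, 130444929 to 130501274), measured 16.3 ± 11.9 and 27.6 ± 21.3 CPM, with overlapping libraries and an edgeR adjusted p of 0.995. Exact permutation p was 0.1 for APEX1 and for CPS1, the smallest that 3 against 3 libraries allow, and 0.7 for ASS1.

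Within the 2 sets, the log2 fold change of APEX1 was -1.41 for KO 65, -2.03 for KO 16 and -1.19 for KO 66. That of CPS1 was -3.53, -3.17 and -1.30 in the same order. ASS1 gave 0.75, -0.22 and 1.37, so its direction did not hold in each KO library. Of the other tested urea cycle genes, ASL, ARG2, NAGS and SLC25A15 had log2 fold changes of -0.14, -0.20, -0.47 and -0.18, and SLC25A13 had 0.20, each with an edgeR adjusted p of 0.995. Within the sets ASL gave 0.12, -0.15 and -0.26, ARG2 gave -0.62, -0.34 and 0.11, NAGS gave 0.39, -0.82 and -0.80, SLC25A15 gave -0.41, -0.18 and 0.05, and SLC25A13 gave 0.02, 0.39 and 0.21. OTC, ARG1 and SLC25A2 were too low to be tested in either line. None of the 7 tested members changed over all genes, and 1 was lower adjusted over the list alone. The list's median was -0.18 (camera adjusted p 0.145), and its direction is not independent evidence, since the study chose the cycle.

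**Figure D1:**
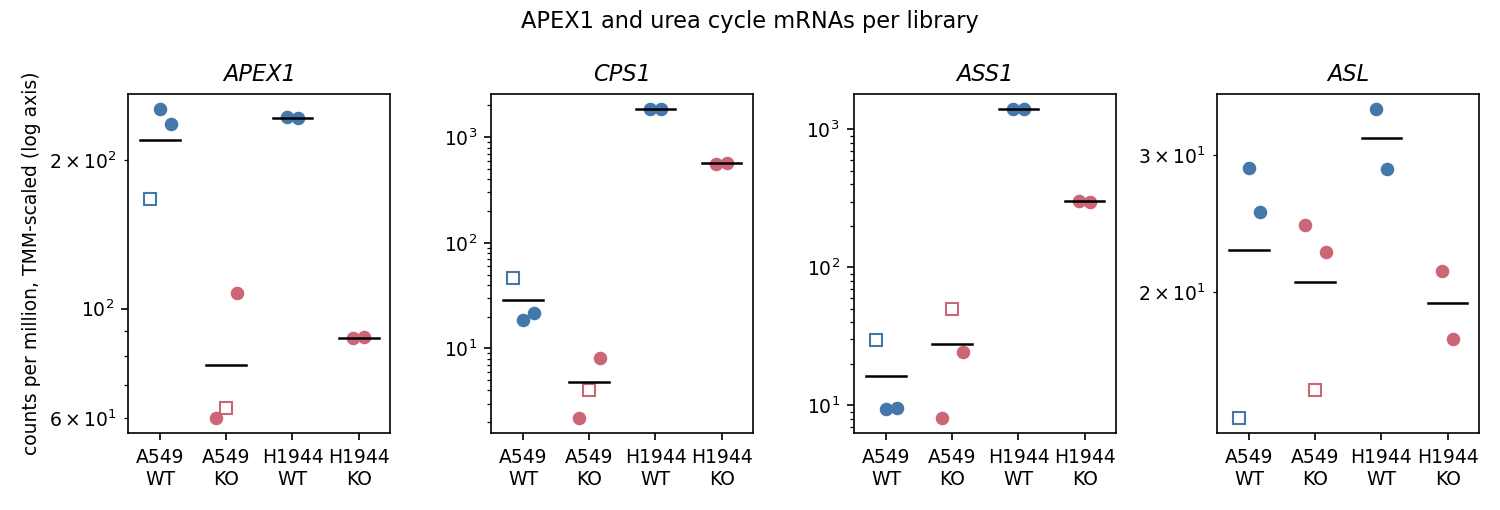
APEX1 and 3 urea cycle mRNAs in TMM-scaled CPM on a log axis, 1 point per library, WT in blue and KO in red, with black bars at the group means. Open squares are A549 WT 1 and KO 65. CPS1 averages 29.02 and 4.79 CPM in A549 WT and KO, and 1855 and 565 CPM in H1944 WT and KO.

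Over all genes 1 of 15806 passed in A549. MAGEA6, a cancer-testis antigen gene (chromosome X, 152766136 to 152769747), rose 12.1-fold, from 4.76 ± 0.463 to 57.8 ± 10.1 CPM (SD, n = 3 each; log2 fold change 3.60, SE 0.23, edgeR adjusted p 0.0157), and was higher in each KO library. Within the sets its log2 fold change was 3.15, 3.79 and 3.82 for KO 65, KO 16 and KO 66. MAGEA3, a near-identical paralog named after its values were seen, measured 0.737 and 7.18 CPM (edgeR adjusted p 0.0768), and reads may have been shared between them. No gene was lower by edgeR, while 895 genes had an unadjusted p under 0.05; limma-voom called 1 gene higher and 0 lower, and DESeq2 called 81 higher and 44 lower. WT and KO libraries were apart for 10.7% of the genes, where chance gives 10%.

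The A549 test had little power and its single call is fragile. On simulated data drawn with the real spread, edgeR recovered 0 of 528 4-fold changes and its 1 call was an unchanged gene, and 52.0% of DESeq2 calls were unchanged genes, so the counts do not show how many A549 genes responded. Without any 1 of the 6 libraries the count of genes was 0, with adjusted p of MAGEA6 between 0.0584 and 0.266, and in the larger set alone it was 0, with 1551 genes at an unadjusted p under 0.05.

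By group, p53 target genes had the smallest camera p in A549, and their median was above 0 in each KO library. Of 12 lists that passed camera in A549, only p53 targets, nucleotide synthesis, mitosis and ribosomal proteins passed without each of the 6 libraries. The 26 genes of the list, which p53 is known to activate, had a median log2 fold change of 0.63, with 25 above 0 (camera adjusted p 2.1e-13, but adjusted p = 0.361 with an estimated correlation). CDKN1A, which arrests the cell cycle, measured 96.7 ± 10.4 CPM in WT and 248 ± 81.0 CPM in KO, and GDF15, a stress cytokine, 59.4 ± 10.1 and 213 ± 96.2 CPM (SD, n = 3 each; edgeR adjusted p 0.521 for both). Within the sets, in the order KO 65, KO 16 and KO 66, CDKN1A gave 1.97, 0.73 and 1.23 and GDF15 2.08, 1.04 and 2.08. BTG2 and BBC3 had log2 fold changes of 1.23 and 1.44. None of the 26 passed over all genes and 3 were higher adjusted over the list alone. By fry the list had an adjusted p of 0.165, and no A549 list passed. Within the sets the list's median was 0.79 for KO 65, 0.63 for KO 16 and 0.51 for KO 66, with 24, 21 and 24 genes above 0, and in a fit of the larger set alone it was 0.48. The 2 sets also differed in this list, by a median of -0.32 for the 4 libraries against WT 1 and KO 65 (camera adjusted p 0.0225; adjusted p = 0.409 with an estimated correlation).

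Epithelial genes had a median of 0.71 in A549 (15 tested, camera adjusted p 0.00405; adjusted p = 0.420 with an estimated correlation), with EPCAM at 22.8 ± 6.997 CPM in WT and 64.2 ± 24.5 CPM in KO, and CLDN3, CDH3 and ESRP1 at log2 fold changes of 1.21, 1.65 and 1.93. CDH3 had only 2 to 10 counts per WT library and 14 to 33 per KO library. ESRP1 overlapped between genotypes, with 14 counts in KO 65 against 30 and 15 in WT 2 and WT 3. Within the sets the list's median was 0.59 for KO 65, 0.22 for KO 16 and 0.15 for KO 66. In the same order EPCAM gave 1.25, 1.51 and 1.61. The median in the larger set alone was 0.32 (camera adjusted p 0.0503), and without KO 16 it was 0.19. The median difference between the sets was 0.85 (camera adjusted p 0.000791, and adjusted p = 0.409 with an estimated correlation). Squamous markers had a median of 1.37 (5 tested, camera adjusted p 0.00174; adjusted p = 0.361 with an estimated correlation), with SOX2 at a log2 fold change of 1.98, DSC3 at 1.37, TP63 at 1.94 and KRT6A at 0.57. Within the sets it was 1.602, 1.75 and 0.75, in the larger set alone 1.29 (camera adjusted p 0.118), and without KO 16 it was 0.76. AP-1 and immediate early genes had a median of 0.24 (21 tested, camera adjusted p 0.0276; adjusted p = 0.443 with an estimated correlation), with ATF3 at 1.41, PHLDA1 at 0.56, PLAUR at 0.55 and HMGA1 at -0.31, and 0.26 in the larger set (camera adjusted p 0.118). Within the sets its median was 0.31, 0.54 and 0.11. The median difference between the sets was -0.38 (camera adjusted p 0.0440, and adjusted p = 0.699 with an estimated correlation). None of these members passed over all genes, and 0, 3 and 0 were higher adjusted over the list alone.

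Proliferation and biosynthesis lists lay below 0 in A549, and none held with an estimated correlation. Mitosis genes had a median of -0.24 (28 tested, camera adjusted p 4.4e-05; adjusted p = 0.420 with an estimated correlation), with CENPA at -0.79, UBE2C at -0.45, CDC20 at -0.51 and PLK1 at -0.35. DNA replication genes had -0.20 (30 tested, 0.00043, and adjusted p = 0.420 with an estimated correlation), with RFC4, POLA2 and RFC2 at -0.35, -0.32 and -0.43 and CCNE1 at 0.50. Nucleotide synthesis genes had -0.18 (23 tested, 0.000882, and adjusted p = 0.420 with an estimated correlation), with RRM2 at -0.72, CAD at -0.56, UCK2 at -0.26 and DHODH at -0.51. Base excision repair genes other than APEX1 had -0.13 (25 tested, 0.0348, and adjusted p = 0.496 with an estimated correlation), with NEIL3 at -0.79, MBD4 at 0.40, PARP2 at -0.43 and PCNA at -0.19. In the larger set alone these 4 medians were -0.17, -0.11, -0.12 and -0.23, and the camera adjusted p was 0.0148, 0.194, 0.0412 and 0.0611. Within the sets, in the order KO 65, KO 16 and KO 66, mitosis gave -0.44, 0.05 and -0.33, replication -0.48, -0.08 and -0.02, nucleotide synthesis -0.38, 0.0061 and -0.20, and base excision repair -0.05, -0.32 and 0.04, so only replication kept its direction in each KO library. Without KO 65 the medians of mitosis, replication and nucleotide synthesis were -0.10, -0.07 and -0.11. No member of the 4 lists passed over all genes or adjusted over the list alone. Median differences between the sets were 0.22 in mitosis (camera adjusted p 0.00449), 0.23 in replication (0.0270), 0.17 in nucleotide synthesis (0.0971) and 0.28 in base excision repair (0.0649). With an estimated correlation none of them passed (adjusted p 0.725 to 0.726).

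NRF2 targets, antioxidant and detoxification genes, had a median of -0.12 in A549 (26 tested, camera adjusted p 0.0163; adjusted p = 0.361 with an estimated correlation). CYP4F11 measured 71.5 ± 1.53 CPM in WT and 31.9 ± 2.66 CPM in KO, and was the 1 member lower adjusted over the list alone. AKR1C3 and AKR1B10 had log2 fold changes of -0.75 and -0.72, and HMOX1 had 1.01. Ribosomal protein genes had a median of -0.32 (52 tested, 6.8e-06, and adjusted p = 0.560 with an estimated correlation), with RPS7, RPS27A, RPS3 and RPL27 at -0.64, -0.65, -0.59 and -0.38. Nuclear genes of respiratory complex I had -0.20 (36 tested, 0.00174, and adjusted p = 0.565 with an estimated correlation), with NDUFA7, NDUFS8, NDUFV1 and NDUFB10 at -0.57, -0.61, -0.65 and -0.49. Genes beside APEX1 had -0.25 (7 tested, 0.0348, and adjusted p = 0.446 with an estimated correlation), with PNP, PARP2, PIP4P1 and OSGEP at -0.44, -0.43, -0.25 and -0.33. CYP4F11 gave -1.15, -1.06 and -1.30 for KO 65, KO 16 and KO 66 within the sets. In the same order NRF2 targets gave -0.16, -0.44 and -0.13, ribosomal proteins -0.07, -0.65 and -0.18, complex I 0.09, -0.62 and -0.16, and genes beside APEX1 -0.63, -0.15 and -0.16. In the larger set alone these 4 medians were -0.15, -0.44, -0.37 and -0.26, and genes beside APEX1 did not pass (camera adjusted p 0.253). Median differences between the sets were 0.69 in ribosomal proteins and 0.60 in complex I, more than between WT and KO. Their camera adjusted p was 1.9e-18 and 8.4e-09, but 0.699 for both with an estimated correlation.

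The other A549 lists did not pass, with camera adjusted p between 0.0825 and 0.811. Their medians were 0.29 for interferon-stimulated genes, 0.44 for replication histones, 0.46 for NF-kB targets, -0.15 for hypoxia targets, 0.61 for fibroblast markers, 0.19 for mesenchymal genes, 0.14 for lung lineage genes, -0.01 for cholesterol synthesis, -0.10 for the integrated stress response and -0.04 for oncogenes with promoter G-quadruplexes. Neuroendocrine markers had 0.17. Arginine, polyamine and proline genes had a median of -0.14 and a mean of 0.04, and leukocyte markers -0.04 and 0.18. Adjusted over the list alone, 1 hypoxia target was lower, and 2 mesenchymal genes, 1 neuroendocrine and 1 fibroblast marker were higher.

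The same question in H1944 gave falls in both large urea cycle mRNAs. APEX1 fell from 244 ± 0.763 to 87.3 ± 0.363 CPM (SD, n = 2 each; log2 fold change -1.48, SE 0.037, edgeR adjusted p 6.4e-19). ASS1 fell from 1405 ± 5.20 to 302 ± 4.08 CPM (log2 fold change -2.22, SE 0.031, 2.8e-23) and CPS1 from 1855 ± 0.745 to 565 ± 10.4 CPM (-1.71, SE 0.030, 1.1e-21). ASL (-0.71), SLC25A13 (-0.70), a mitochondrial aspartate and glutamate carrier, and NAGS (-0.63), which makes the activator of CPS1, fell too. SLC25A15 (0.45), the ornithine carrier, and ARG2 (0.31), a mitochondrial arginase, rose. All 7 tested members passed over all genes and adjusted over the list alone, 5 lower and 2 higher, and the direction is not independent evidence. The list's median was -0.70 (fry adjusted p 0.000425), and its camera call is unstable. It did not pass (adjusted p 0.0787; adjusted p = 0.364 with an estimated correlation), but did without the low-count filter (0.0432) and without WT 1, WT 2, KO 1 or KO 2 (2.9e-12, 0.000163, 1.1e-06 and 2.3e-06). The edgeR adjusted p of NAGS was 0.0496, and NAGS did not pass with the replicate block, by DESeq2 or without H1944 WT 2, KO 1 or KO 2.

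Of 16626 genes in H1944, 5522 rose and 5642 fell, 1680 and 1873 of them at least 2-fold. With the replicate block the counts were 5568 and 5660, and deviations of equally numbered libraries correlated at 0.0128 across genes, which are not independent replicates. With all 10 libraries in one fit 1177 rose and 1345 fell. On simulated data 10.4% of the H1944 calls were unchanged genes. The 4 libraries show only the spread between these 2 pairs, with a biological coefficient of variation of 4.74% against 39.0% in A549. With the processing set in the A549 fit it was 24.2%.

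The largest rises in H1944 included genes with 0 counts in both WT libraries. POSTN, a matrix protein, was at least 105-fold higher in KO (14.7 CPM before scaling), CLMAT3 at least 61.6-fold, TTC29 at least 46.7-fold, ERVV-2 at least 43.6-fold and OLR1 at least 38.8-fold. LHFPL6 and IGFL2, with 1 WT count each, had ratios of 1437 (95% interval 258 to 56786) and 1076 (193 to 42525). SPARC, a matrix protein, rose 838-fold, from 0.278 to 235 CPM, and EPB41L3 and MARCHF4 rose by 8.55 and 8.46 on the log2 scale. The largest falls included UGT2B4, a glucuronosyltransferase, from 508 CPM before scaling to 3 counts, a ratio of 10015 (3426 to 48567). IRX4, PHACTR3 and CEACAM5 had 0 KO counts and were at least 174-fold, 127-fold and 121-fold lower, and MUC5B-AS1 and EPHA3 at least 57.2-fold and 56.3-fold. NOL4 had a ratio of 1858 (333 to 73436), and TMPRSS15 fell by 9.94 on the log2 scale. FXYD2 and the readthrough gene FXYD6-FXYD2 overlap and had ratios of 1881 (643 to 9124) and 1865 (638 to 9048).

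Epithelial and lung genes fell and mesenchymal genes rose in H1944. Of 16 tested epithelial genes 12 fell and 2, KRT18 and KRT8, rose (median -2.35, camera adjusted p 0.00881; adjusted p = 0.330 with an estimated correlation). CDH1, which encodes E-cadherin, fell by 4.72 on the log2 scale, EPCAM by 6.21, CLDN4 by 2.76 and ELF3 by 2.12. Of 19 mesenchymal genes 16 rose and 0 fell (median 1.603, camera adjusted p 1.5e-08; adjusted p = 0.152 with an estimated correlation), among them SPARC, FN1 at 5.12, MMP2 at 4.55 and VIM, which encodes vimentin, at 1.76. All 10 lung lineage genes fell (median -4.10, or -3.87 with 1 gene at its bound; camera adjusted p 4.1e-06, and adjusted p = 0.284 with an estimated correlation), with the mucin MUC5B at -6.81, CEACAM6 at -6.12 and HOPX at -5.17. Of 5 squamous markers 4 fell, among them SOX2 and TP63 (median -4.10, camera adjusted p 0.131). Fibroblast markers, which could report other cells, went both ways, with 3 risen and 2 fallen of 8 (median 0.07), and 1 of 3 leukocyte markers rose (median 0.95). Counts adjusted over the list alone were the same for each of these 6 lists. Without H1944 WT 1 the camera adjusted p of the epithelial list was 0.0720.

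Interferon and p53 genes rose together in H1944. All 27 tested interferon-stimulated genes rose (median 2.53, camera adjusted p 2.0e-14; adjusted p = 0.152 with an estimated correlation), with IFI6 24.7-fold higher, from 19.1 ± 0.0555 to 473 ± 3.08 CPM, MX1 at a log2 fold change of 4.27, IFIT1 at 3.92 and IFI44L at 2.52. Of 26 p53 targets 25 rose (median 1.28, camera adjusted p 1.8e-12; adjusted p = 0.152 with an estimated correlation). CDKN1A rose 7.26-fold, from 99.8 ± 4.05 to 725 ± 7.73 CPM, and GDF15, TIGAR and MDM2 rose by 2.56, 2.24 and 1.12. Of 22 AP-1 and immediate early genes 16 rose and 3, FOS, EGR1 and ATF3, fell (median 0.72, camera adjusted p 8.9e-05; adjusted p = 0.250 with an estimated correlation), with PLAU at 2.69, PHLDA1 at 2.31, FOSL1 at 1.72 and FOSL2 at 1.59. Counts adjusted over the list alone were the same for these 3 lists.

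Cell cycle genes fell in H1944. Of 28 mitosis genes 27 fell, and 28 adjusted over the list alone (median -0.83, camera adjusted p 1.7e-13; adjusted p = 0.190 with an estimated correlation), with CENPF at -1.50, MKI67 at -1.37, KIF11 at -1.26 and TOP2A at -1.20. Of 30 replication genes 28 fell and CCNE1 rose (median -0.66, camera adjusted p 1.1e-09; adjusted p = 0.152 with an estimated correlation), with POLA1 at -1.29, RFC5 at -1.17, MCM4 at -1.12 and MCM7 at -1.10. Of 10 replication histones 7 rose, and 1 fell adjusted over the list alone (median 1.13, camera adjusted p 0.0336, and adjusted p = 0.324 with an estimated correlation), with H2BC4 at 2.31, H2BC5 at 2.05, H2AC6 at 1.75 and H1-2 at 1.58. The list was fixed as a check of RNA selection, since replication-dependent histone mRNAs mostly lack poly(A) tails. Whether these members also made polyadenylated mRNAs was not tested. Ribosomal RNA was also higher in H1944 KO (0.308% and 0.316%) than in WT (0.139% and 0.231%). A difference in RNA selection between WT and KO libraries therefore cannot be told apart from a change in the cells. The same limit holds for the histones between lines. Without H1944 WT 1 the camera adjusted p of the histones was 0.120.

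Metabolic lists in H1944 moved in part. Of 26 NRF2 targets 17 fell and 5 rose (median -0.30, camera adjusted p 0.000786; adjusted p = 0.250 with an estimated correlation): the reductase AKR1B10 fell by 3.39, GSR by 1.68 and UGDH by 1.18, and NQO1 rose by 1.08. Of 52 ribosomal protein genes 48 rose and 2 fell (median 0.40, camera adjusted p 7.6e-15; adjusted p = 0.383 with an estimated correlation), with RPS19, RPL38 and RPL27 at 0.76, 0.69 and 0.62. Of 23 cholesterol synthesis genes 15 fell and 6 rose (median -0.23, camera adjusted p 0.0343; adjusted p = 0.324 with an estimated correlation), with FDFT1, CYP51A1 and HMGCS1 at -0.84, -0.81 and -0.60 and STARD4, a sterol carrier, at 1.72. Without H1944 WT 1, KO 1 or KO 2 the camera adjusted p of the cholesterol list was 0.103, 0.155 and 0.149. Counts adjusted over the list alone were the same for these 3 lists.

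The other H1944 lists did not pass camera, with adjusted p between 0.0956 and 0.929. Since 11164 of 16626 genes passed in H1944, a fry pass does not set a list apart from other genes. Fry passed the arginine list (adjusted p 0.00293), nucleotide synthesis (0.000973), base excision repair (0.0109) and hypoxia targets (0.00666). It also passed neuroendocrine markers (0.00908) and the G-quadruplex oncogenes (0.0138). NF-kB targets (0.0742), the integrated stress response (0.254), complex I (0.168) and genes beside APEX1 (0.0839) did not pass fry. Arginine, polyamine and proline genes had 11 higher and 6 lower (median 0.13), nucleotide synthesis 4 and 11 (-0.08), base excision repair 6 and 10 (-0.06), hypoxia targets 11 and 6 (0.20) and NF-kB targets 12 and 5 (0.38). Neuroendocrine markers had 4 higher and 1 lower (1.00), oncogenes with promoter G-quadruplexes 5 and 6 (-0.14), complex I 14 and 13 (-0.06) and the genes beside APEX1 2 and 1 (-0.08). The integrated stress response had 9 and 10, with a median of 0.09 and a mean of -0.02. Counts adjusted over the list alone were the same for these 10 lists.

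**Figure D2:**
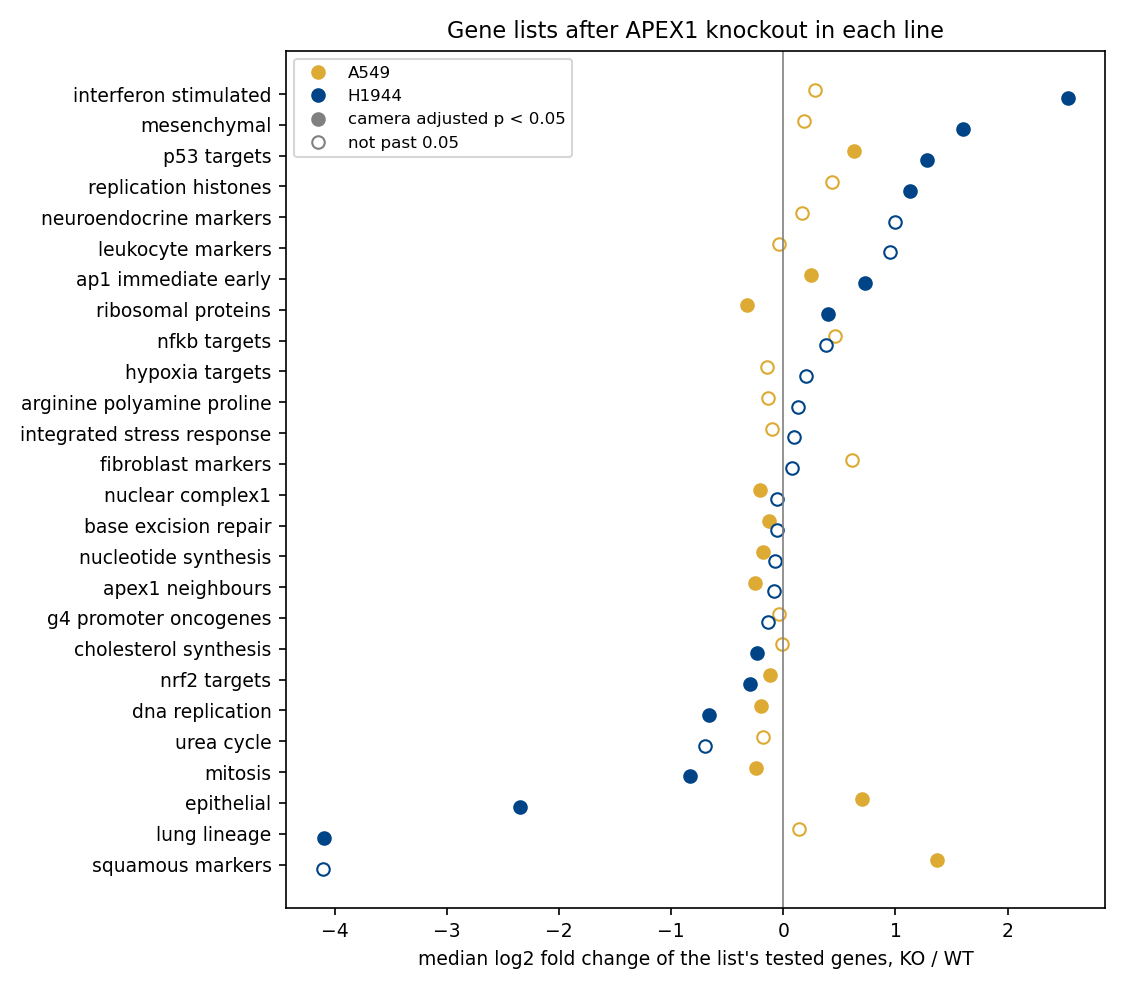
Median log2 fold change (KO over WT) of the tested genes of each list, with A549 in yellow and H1944 in blue. Filled points passed camera at the preset correlation, and none passed with an estimated correlation. Interferon-stimulated genes lie at 2.53 in H1944 and 0.29 in A549, and p53 targets at 1.28 and 0.63.

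**Figure D3:**
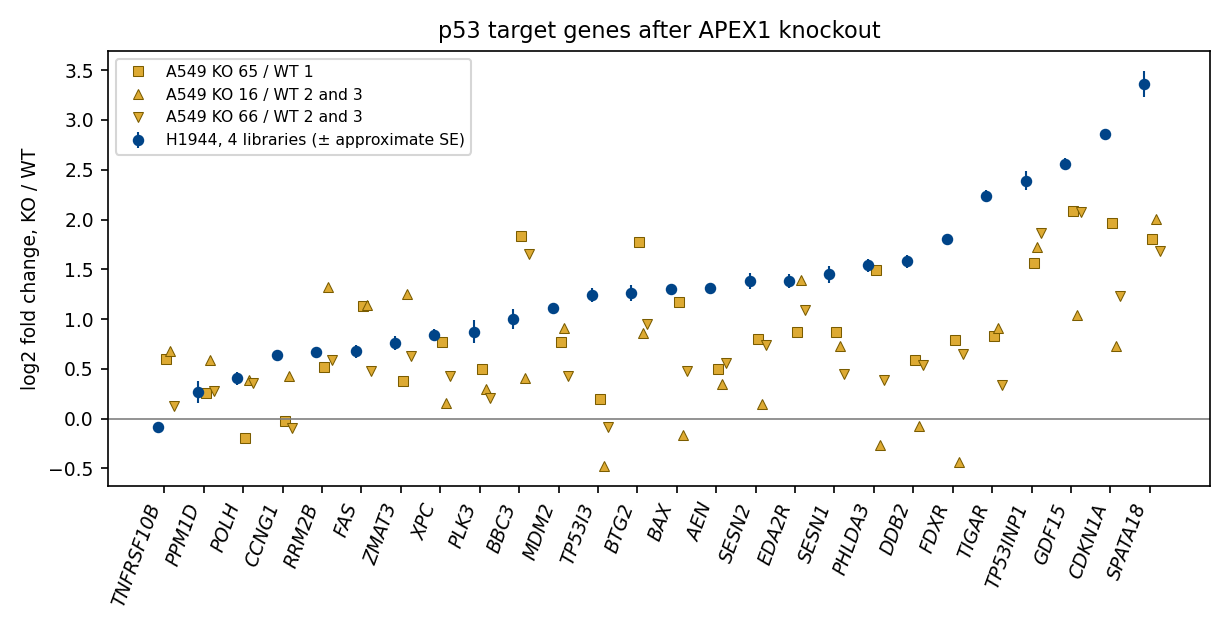
Log2 fold change of the 26 p53 targets, with H1944 as circles and approximate standard errors and each A549 KO library against WT of its own set as yellow squares and triangles. The medians of the 3 A549 KO libraries are 0.79, 0.63 and 0.51.

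The last question was whether the lines responded alike, tested as the A549 change minus the H1944 change. The interferon list, which rose in H1944, and the lung lineage list, which fell there, differed between the lines, and neither list passed in A549. The interferon list had a median difference of -1.86 (camera adjusted p 4.0e-13; adjusted p = 0.0307 with an estimated correlation), with 12 of 27 genes past the test, among them IFI6 (-4.99), IFIT1 (-4.08) and MX1 (-3.59). Lung lineage genes had 3.89, or 3.85 with 2 genes at their bound (camera adjusted p 3.2e-08; adjusted p = 0.0294 with an estimated correlation), with 8 of 11 past the test, among them MUC5B (6.41) and CEACAM6 (7.91). Epithelial genes had 2.96 and mesenchymal genes -1.48 (camera adjusted p 4.8e-06 and 1.7e-06; adjusted p = 0.264 and 0.164 with an estimated correlation), with EPCAM at 7.66 and VIM at -2.26. The difference of ASS1 was 2.99 (SE 1.00, edgeR adjusted p 0.118), of CPS1 -0.88 (0.524) and of APEX1 -0.06 (0.966), and none of the 3 passed over all genes. Adjusted over the urea cycle list alone, ASS1 and SLC25A13 (0.88) were higher and SLC25A15 (-0.65) was lower. The NF-kB list did not pass, and had a median of 0.04, a mean of 0.48 and a camera direction below 0.

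Of 17677 genes, 725 had a higher and 503 a lower change in A549. By fitted value, which is no bound where a group has 0 counts, CEACAM5 headed the differences upward: its A549 libraries had 17.8 ± 10.0 CPM in WT and 92.3 ± 68.1 CPM in KO, and it was lost in H1944. UGT2B4, CYP2B7P, NPY5R and IRX4 followed, and ARMCX1, LHFPL6, CADM3-AS1, PTPRD and IGFL2-AS1 headed those downward. UGT2B4, CYP2B7P, NPY5R, IRX4, ARMCX1 and CADM3-AS1 had 0 to 7 counts in each A549 library, so the A549 part of their fitted differences is unreliable. PTPRD, a receptor phosphatase, had 102, 29 and 21 counts in A549 WT 1, 2 and 3 and 0 in each KO library, and 13.6 and 14.9 CPM in H1944 WT and KO. Without A549 WT 1 the count of genes was 2892, and without H1944 KO 1 it was 397. With the replicate block it was 761.

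By edgeR in the fits of each line alone, MAGEA6 was the 1 gene called in both lines in the same direction. It rose 4.70-fold in H1944, from 6.33 to 29.8 CPM, and the change was larger in A549 by 1.34 (edgeR adjusted p 0.0146). Independent lists would share 0.339 genes (Fisher's exact p 0.339), and with 1 A549 gene the test could not have passed. By DESeq2 32 genes were shared higher (20.4 expected, Fisher's exact p 0.00367) and 25 lower (12.2 expected, 5.3e-05). One fit of all 10 libraries shared 4 higher (0.666 expected, 0.00297) and 1 lower (0.457 expected, 0.378). These tests treat genes as independent, and many DESeq2 calls in A549 were false on simulated data. Fold changes were compared across 14985 genes tested in both lines, which are not independent replicates. They correlated at 0.0090 (Pearson) and -0.0102 (Spearman), and with the A549 set as a covariate at 0.0069 and -0.0218. Pearson correlations with H1944 were 0.0902 for KO 65, -0.119 for KO 16 and 0.0972 for KO 66, each against WT of its set. Between A549 KO libraries, over 15806 genes, they were 0.173 (65 and 16), 0.351 (65 and 66) and 0.355 (16 and 66, which share WT libraries).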

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

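Tests of the 2 A549 library sets and of fibroblasts were chosen after the results they bear on were seen; the other tests in this part were set before. The results below differ between the lines by a test of the difference itself, the A549 change minus the H1944 change.

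For 12 lists camera passed for the difference, and with an estimated correlation only the interferon and lung lineage lists did. Fry passed these and the epithelial (adjusted p 0.00447), mesenchymal (0.0179), squamous (0.00447), hypoxia (0.000401) and histone (0.0198) lists. It did not pass p53 targets (0.0846), replication (0.0848), mitosis (0.0848), AP-1 genes (0.106) or ribosomal proteins (0.381). The medians were -1.86 for interferon-stimulated genes, 3.89 for lung lineage, 2.96 for epithelial genes, -1.48 for mesenchymal genes, 4.18 for squamous markers, -0.64 for p53 targets, 0.46 for DNA replication, 0.57 for mitosis, -0.43 for AP-1 and immediate early genes, -0.26 for hypoxia targets, -0.73 for ribosomal proteins and -0.51 for replication histones. With genes of an empty group at their bound, the medians were 3.85 for lung lineage, 3.06 for squamous markers, -0.52 for AP-1 genes and -0.85 for histones. Adjusted p with an estimated correlation was 0.264 for epithelial genes and histones, 0.164 for mesenchymal genes and squamous markers, 0.409 for p53, 0.445 for replication and AP-1, 0.461 for mitosis, 0.182 for hypoxia and 0.763 for ribosomal proteins.

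The named genes given here differed as well. Epithelial, lung and squamous genes were higher in the A549 comparison: EPCAM by 7.66 on the log2 scale, CDH1 by 5.40, ESRP1 by 8.69, CLDN3 by 3.44, CLDN4 by 3.44, CDH3 by 4.06, ELF3 by 2.48, MUC5B by 6.41, CEACAM6 by 7.91, SOX2 by 7.80, TP63 by 3.82 and KRT6A by 4.63. MAGEA6 (1.34), AKR1B10 (2.63), GSR (1.56), ATF3 (2.58), FDFT1 (1.03) and RFC5 (0.92) were higher too. Interferon genes were lower, with IFI6 at -4.99, IFIT1 at -4.08 and MX1 at -3.59. SPARC (-6.25), VIM (-2.26), PLAU (-2.80), PHLDA1 (-1.77), FOSL1 (-1.66), CDKN1A (-1.53), TIGAR (-1.54), NQO1 (-1.22), CYP4F11 (-0.79), STARD4 (-1.72), H2BC5 (-1.59), H2BC4 (-2.66) and MARCHF4 (-8.93) were lower too. Another 15 genes, with at most a few counts in at least 1 group, had fitted differences that depend on the prior count and are no bounds. They were CEACAM5 at 13.43, UGT2B4 at 12.30, CYP2B7P at 11.34, NPY5R at 10.81, IRX4 at 10.80, MUC5B-AS1 at 9.91, FXYD2 at 9.47, FXYD6-FXYD2 at 9.45, ARMCX1 at -12.32, LHFPL6 at -10.86, CADM3-AS1 at -8.96, PTPRD at -8.95, IGFL2-AS1 at -8.94, IGFL2 at -7.71 and CLMAT3 at -6.94. ESRP1 and SOX2 also had few counts in H1944 KO. MARCHF4 (4 and 3) and SPARC (5 and 7) had few in H1944 WT 1 and 2, so their fitted differences share this limit.

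The 2 sets of A549 libraries may in part be counted differently: in chromosome regions with alternate haplotype sequences, 44.0% of expressed genes were over 16-fold lower in WT 1 and KO 65, against 0.843% elsewhere. It may also account for part of the 93 such genes elsewhere, of which 74.2% were low in H1944 too (78.8% in the regions), but NF-kB targets, higher in WT 1 and KO 65, argue against it as the whole cause: 15 of 16 were lower in the other 4 libraries and 10 passed (median -1.69; adjusted p = 0.409 for the list with an estimated correlation). Weaker poly(A) selection in the other 4 libraries would raise mRNAs without poly(A) tails. The 8 tested histone mRNAs had a median log2 difference of -0.11, while ribosomal RNA differed by 4.79. Polyadenylated forms of these histones were not told apart, and ribosomal RNA may also be counted differently between the sets. This test therefore does not decide the question. H1944 cells in WT 1 and KO 65 are argued against by 56 genes silent in H1944 WT and at a mean of at least 5 CPM in the other 4 libraries. Of these genes 82.1% reached 1 CPM in both WT 1 and KO 65. They were chosen against H1944 and the share expected in other lines is not known, so other lines are not excluded. Culture conditions and handling stay open and were not tested.

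Most tested genes passed in the fit of H1944 alone (2522 of 17677 in one fit of all 10 libraries), with most listed epithelial genes lower, KRT8 and KRT18 higher, and most mesenchymal genes higher (adjusted p = 0.330 and 0.152 for the 2 lists with an estimated correlation). Depth and a trend on GC content and length are argued against: after thinning to the smallest library 10833 genes passed (11164 in full), and of the 15619 genes with a GC value 3201 were changed at least 2-fold after removal of the trend, which explained 1.54% of the variance, against 3328 before. Fibroblasts among the KO cells are argued against by COL1A1, at 10.2 CPM in WT and 5.77 CPM in KO, though POSTN, COL3A1 and DCN rose. Loss of APE1 may be the cause. Selection of a subpopulation or clone with the KO stays open, since the labels do not say how many clones the 2 KO libraries represent. The line identity of the H1944 KO cells was not tested.

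The p53 list had a median above 0 in each A549 KO library, with 24, 21 and 24 of 26 genes above 0 for KO 65, KO 16 and KO 66 and the lowest of the 3 within-set medians at 0.51, which argues against the set difference as the whole cause, though no member passed over all genes and the list did not with an estimated correlation (adjusted p = 0.361). Level, length and GC content are argued against too, since the list's median lay at percentile 100 of 10000 matched random lists. Within the sets the 95th percentile of matched lists was 0.158 for KO 65, 0.176 for KO 16 and 0.0717 for KO 66, below the p53 medians. KO 16 and KO 66 share WT 2 and WT 3, so their medians are not independent. The 6 libraries have 10 splits into 3 and 3, which cannot give a share under 0.05. Of these, 1 gave a p53 list p as small, the real one, at a negative log10 p of 14.1 against 4.67 for the highest other, and real and other splits called 12 and up to 10 lists. For genes 2 splits gave as many, the real one with 1 and WT 1, KO 16 and KO 65 with 5188, which points to a structure of the samples; DNA damage after loss of APE1 may explain the p53 genes but was not measured.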

How the results depend on the processing

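The A549 set covariate, the larger A549 set alone and leaving out ribosomal RNA genes were chosen after the data were seen. Where a value below moved, the cause was not tested. In A549, DESeq2 called 81 genes higher and 44 lower (77 and 33 at least 2-fold), one fit of all 10 libraries 10 and 6 (10 and 5), no filter 2 higher, the larger set 0, and the covariate 1 lower, NTRK3. Without any 1 library 0 genes were higher in A549 (0 to 0 at 2-fold; edgeR, 400 to 2321 genes at an unadjusted p under 0.05). H1944 counts moved by over 1.5 times in one fit of all 10 libraries, to 1177 and 1345 (950 and 1099 at least 2-fold), where the spread of A549 enters the test. They moved less by DESeq2 (4591 and 4722), with library size alone (5078 and 6033) and without 1 library (5017 to 5334 higher and 5113 to 5341 lower). Without 1 H1944 library a group has 1 sample, which is assumed to vary like the other group. Between lines, 2318 genes differed by DESeq2, 761 with the replicate block, 2759 with the covariate, 3394 in the larger set and 397 to 2892 without 1 library. Shared genes were 32 higher (20.4 expected) and 25 lower (12.2 expected) by DESeq2, and 4 (0.666 expected) and 1 (0.457 expected) with all 10 libraries. They were 2 higher without the filter (0.545 expected), 0 at an adjusted p under 0.01 and 0 without 1 A549 library. On simulated A549 data 52.0% of DESeq2 calls were unchanged genes, so its counts are no support.

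Medians of lists and of single genes changed sign as follows, with 1 list that gained a call. Without the filter, A549 lung lineage was -0.0296 and leukocyte markers 1.78, H1944 leukocyte markers were -0.80, the H1944 urea cycle list passed camera at -0.70, and between lines leukocyte markers were 2.56, neuroendocrine markers -0.57 and fibroblast markers 0.65. With the stricter filter A549 neuroendocrine markers were -0.24. Between lines, scaling by library size gave 0.0111 for base excision repair, 0.0416 for the integrated stress response and 0.043 for APEX1. The covariate gave -0.18 for NF-kB, and the larger set -0.054 for NF-kB, -0.24 for the urea cycle and -0.24 for NAGS. Without 1 library the A549 ranges were -0.40 to 0.0001 for the urea cycle, -0.18 to 0.0373 for the integrated stress response, -0.44 to 1.29 for NF-kB, -0.33 to 0.17 for cholesterol, -0.10 to 0.44 for mesenchymal genes, -0.37 to 0.54 for neuroendocrine and -0.14 to 0.0811 for leukocyte markers, -0.40 to 0.0728 for ASL and -0.58 to 0.11 for ARG2. In H1944 they were -0.77 to -0.56 for the urea cycle, which passed camera without any 1 library, and -0.17 to 0.012 for genes beside APEX1. Between lines they were -0.14 to 0.35 for the urea cycle and for NAGS, -0.21 to 0.0092 for base excision repair, -0.15 to 0.0057 for the integrated stress response, -0.96 to 1.47 for NF-kB, -0.073 to 0.29 for cholesterol, -0.60 to 0.68 for neuroendocrine, -0.56 to 0.25 for fibroblast and -0.72 to 1.63 for leukocyte markers, and -0.39 to 0.10 for APEX1.

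Camera calls changed under other alternatives too. In A549 NF-kB targets passed with the covariate (0.00561), fibroblast markers without the filter (0.0261) and histones with the stricter filter (0.0438), and genes beside APEX1 did not pass without the filter (0.0987). In the larger set base excision repair (0.0611), replication (0.194), AP-1 genes and squamous markers (0.118 each), epithelial genes (0.0503) and genes beside APEX1 (0.253) did not pass. H1944 squamous markers passed with the stricter filter (0.0494). Between lines histones did not pass with the covariate (0.0696) or the larger set (0.259), nor hypoxia targets with the larger set (0.0520), and complex I passed with the larger set (0.00533).

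Without 1 library, medians of called A549 lists ran from 0.47 to 0.78 for p53 targets, 0.19 to 0.75 for epithelial genes, 0.76 to 1.46 for squamous markers, 0.17 to 0.46 for AP-1 genes, -0.44 to -0.10 for mitosis, -0.30 to -0.07 for replication, -0.26 to -0.11 for nucleotide synthesis, -0.27 to -0.07 for base excision repair, -0.28 to -0.12 for NRF2 targets, -0.57 to -0.16 for ribosomal proteins, -0.47 to -0.07 for complex I and -0.40 to -0.09 for genes beside APEX1. The low ends in size came without KO 16 for epithelial and squamous genes and NRF2 targets, and without KO 65 for p53 targets, mitosis, replication, nucleotide synthesis, ribosomal proteins and genes beside APEX1. They came without WT 3 for AP-1 genes and base excision repair and without WT 2 for complex I. Between lines AP-1 genes ran from -0.67 (without A549 KO 65) to -0.38, and histones from -1.21 (without H1944 WT 2) to -0.30 (without A549 WT 1).

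Of the 12 A549 lists that camera called at the preset correlation, only p53 targets, nucleotide synthesis, mitosis and ribosomal proteins passed without each of the 6 libraries. Without WT 1 the camera adjusted p was 0.178 for NRF2 targets, 0.317 for epithelial genes and 0.339 for squamous markers, and genes beside APEX1 did not pass. Without WT 2 it was 0.131 for base excision repair, 0.0616 for AP-1 genes and for genes beside APEX1, and 0.201 for complex I; without WT 3 it was 0.135, 0.0546, 0.0629 and 0.142 for base excision repair, AP-1, genes beside APEX1 and complex I. Without KO 16 it was 0.159 for base excision repair, 0.0880 for NRF2 targets and 0.0823 for AP-1 genes. Without KO 65 it was 0.234 for base excision repair, 0.168 for replication, 0.367 for AP-1 genes, 0.108 for complex I and 0.275 for genes beside APEX1, and without KO 66 it was 0.0581 for NRF2 targets and 0.0618 for epithelial genes. NF-kB targets passed without KO 16 or KO 66, cholesterol synthesis and fibroblast markers without KO 16, and interferon and mesenchymal genes without KO 66. In H1944 hypoxia targets passed without WT 1, KO 1 or KO 2. Between lines hypoxia targets did not pass without A549 WT 1 or KO 66 (0.0908 and 0.0757), nor histones without A549 WT 1, KO 65 or KO 66 or H1944 WT 1 (0.146, 0.0950, 0.0509 and 0.105), and complex I passed without A549 WT 1.

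Over all alternatives of the named genes and lists, 1173 values for A549, 1214 for H1944 and 763 between lines kept direction and side of the threshold, 48, 35 and 38 lost their call, 19, 9 and 15 gained one, and 17, 2 and 37 changed sign. Thinned to the smallest H1944 library, 10679 of the 11164 genes still passed, so depth limits few of those calls.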

Other observations

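A hypothesis from the title was that genes with G-quadruplex motifs would change more often in H1944 KO; its test was set before the result was seen. Within strata of GC content and expression, the odds ratio of a motif in the first 500 bases of the transcript was 1.03 (95% interval 0.939 to 1.13) for genes that fell and 1.03 (0.941 to 1.12) for genes that rose. Before stratification the odds ratios were 0.862 and 1.31, so GC content and expression accounted for the apparent difference. Of the 10 urea cycle genes, 1, NAGS, had a motif, on the antisense strand. Promoters were not searched, so this does not speak to motifs upstream of the transcript.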
